A study of Bos taurus with 15 samples.

How the data were processed

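Pieces of bovine ovarian cortex, the outer layer of the ovary that holds small follicles in a collagen-rich stroma, were sampled uncultured (day 0) or after 2 or 4 days of culture with recombinant human follicle-stimulating hormone (FSH) at 100 ng/ml or with its vehicle. The labels name 5 groups of 3 libraries each: day 0, vehicle day 2, FSH day 2, vehicle day 4 and FSH day 4. Per the labels' protocols, total RNA was made into 3′ tag libraries with the QuantSeq forward kit, which reads 1 stretch near the 3′ end of each transcript, with unique dual indexes and a module that adds molecular identifiers, and all libraries were sequenced in 1 lane. The submitters' processing notes name bcl2fastq, FastQC 0.11.2 and Trimmomatic and the builds UMD3.1 and bosTau8. The aligner, the counting program, its strand setting, the gene annotation and whether molecular identifiers were collapsed are not given in the sources used here. Counting intervals and floors printed below cover counting error only.

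The authors deposited 1 table of whole-number counts per gene symbol, not normalized, with 1 column per library. It held 13930 symbols, of which 13492 matched a cattle reference gene table (assembly ARS-UCD2.0) directly and 345 through a synonym. That assembly is not the authors' build, so no coordinates were taken from it. Of these symbols, 1744 were at 0 in all 15 libraries. These included GAPDH, CD68 and AMH; since GAPDH is used by nearly every cell, a 0 here is read only as listed at 0. The symbols MKI67, TOP2A and WT1 and genes of the mitochondrial genome were not analysed here. Reads of overlapping or antisense genes and of near-identical copies cannot be separated in counts of this kind.

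Total counts ran from 711446 (day 0 replicate 1) to 1423935 (day 0 replicate 2), with a median of 1244528. Genes were kept by edgeR's filterByExpr on the 5 groups, which left 8207. Counts were scaled by TMM factors and tested in edgeR 4.0.16 under R 4.3.3 by the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in a single model with 5 group means and 10 residual degrees of freedom, so that all groups shared an estimate of the spread. The common biological coefficient of variation was 25.8%. Fold changes are on the log2 scale with their standard error (SE); adjusted p-values are Benjamini-Hochberg values over the 8207 genes of a comparison, with a threshold of 0.05. Levels are TMM-scaled CPM unless called plain, as mean ± SD over the 3 libraries of a group. For a gene at 0 in a whole group the fold is a bound against a floor of 3 counts over that group; with 1 to 3 counts in a group the ratio is given with a 95% counting interval.

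The comparisons were vehicle day 2 and vehicle day 4 against day 0, vehicle day 4 against vehicle day 2, FSH against vehicle at each day, the mean of both FSH effects, their difference (the interaction), and, as counts of calls only, both FSH groups against day 0 and against each other. For 30 gene lists (pathways, cell types and stress responses) the camera test of limma 3.58.1 asked whether members moved differently from other genes, with a preset inter-gene correlation of 0.01; the test was repeated with an estimated correlation and with fry, which asks whether members move, on balance, in 1 direction. The mitochondrial genome list had 0 members in the table, so 29 lists were tested, and their p-values were adjusted over the lists of a comparison. Adjustment of member genes was also made over the list alone. The lists, the comparisons, the tests and the rule for named genes were fixed before the data were examined. That rule takes the largest rises and falls (8 each way for both vehicle comparisons with day 0 and both FSH effects, 5 for vehicle day 4 against day 2 and the FSH mean, 3 for the interaction) among genes past the threshold whose groups do not overlap and that reach a mean of 10 CPM. It also takes the 4 genes of smallest p where none passes, up to 4 members of smallest p per list, and FSHR, CYP19A1, AMH, INHBA, GDF9, BMP15, DDX4, MKI67 and STAR wherever measured. Some genes that this rule takes are not reported here.

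The labels give replicates 1 to 3 in every group, and day 0 tissue was frozen on the day each culture began, so the numbers were taken to mark cultures started together, which the labels do not say in so many words. Deviations from the group means, correlated across genes, ran from -0.2199 to 0.4398 with a median of 0.189 over the 30 pairs of libraries with the same number (18 were above 0.1) and of -0.0654 over the 60 pairs with different numbers; 13 of the 15 libraries correlated best with a library of their own number. A fit with the replicate number as a block was therefore run as an alternative, with 8 residual degrees of freedom. Replicate pairs of a group differed far beyond sampling noise (chi-square over degrees of freedom 4.45 to 20.01), so none was a copy of another. The labels do not say whether replicates came from different animals, and p-values measure the spread between these libraries.

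Other alternatives were DESeq2 1.42.0 (Wald test), limma-voom, DESeq2 size factors or upper-quartile factors in edgeR, no filter, a filter of 5 CPM in 3 libraries, non-robust dispersion, models of the compared groups only, and leaving out each library or each replicate number. Single libraries were left out of the gene tests only; replicate numbers were left out of both gene and list tests. The gene tests were tried on simulated counts with 200 changed genes. This covered the vehicle comparisons, FSH against vehicle at each day and the FSH mean. DESeq2 and limma-voom were tried at 2-fold changes only. Steps not tried this way included the interaction, the FSH groups against day 0, fry, the estimated correlation, the replicate block and the leave-outs. For vehicle day 2 against day 0 edgeR recovered 0% of genes changed 1.5-fold, 9.5% of those changed 2-fold and 76% of those changed 4-fold, among 8095, 8094 and 8067 genes. In the data 2618 genes passed in this comparison, so its adjusted threshold was less strict than with 200 changed genes. The simulated recovery therefore does not carry over to it.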

Results

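The data were 3′ tag counts from 15 libraries of bovine ovarian cortex in 5 groups of 3: uncultured tissue (day 0) and tissue cultured for 2 or 4 days with vehicle or with FSH, the pituitary hormone that acts on granulosa cells of the follicle. Totals lay between 711446 and 1423935 counts per library. The main axis of variation separated uncultured from cultured libraries and held 46% of the variance, and the next held 12.5%. On that next axis day 0 replicate 1 lay at -27.82 and the other day 0 libraries at 27.12 and 26.33, while the vehicle day 4 libraries were spread out, at -25.83, -1.82 and -47.22 for replicates 1, 2 and 3. Day 0 replicate 1 had the lowest total and 9.18% of its counts in ribosomal protein genes, against 15.4% and 14.11% in the other day 0 libraries. Vehicle day 4 replicate 3 had 19.12%, against 15.87% and 12.1% in the other vehicle day 4 libraries. A few abundant genes, chosen after their values were seen, also set libraries apart, given here in plain CPM without the TMM factors. RN45S, the precursor of ribosomal RNA, was at 1583 to 4502 CPM at day 0 and 656 to 1547 in the 12 cultured libraries, and GPC5 at 1671 to 7864 and 259 to 811. CLASP1 was at 7660 plain CPM in day 0 replicate 1 and 7212 in vehicle day 4 replicate 3, with 1406 to 4692 in the others.

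**Figure D1:**
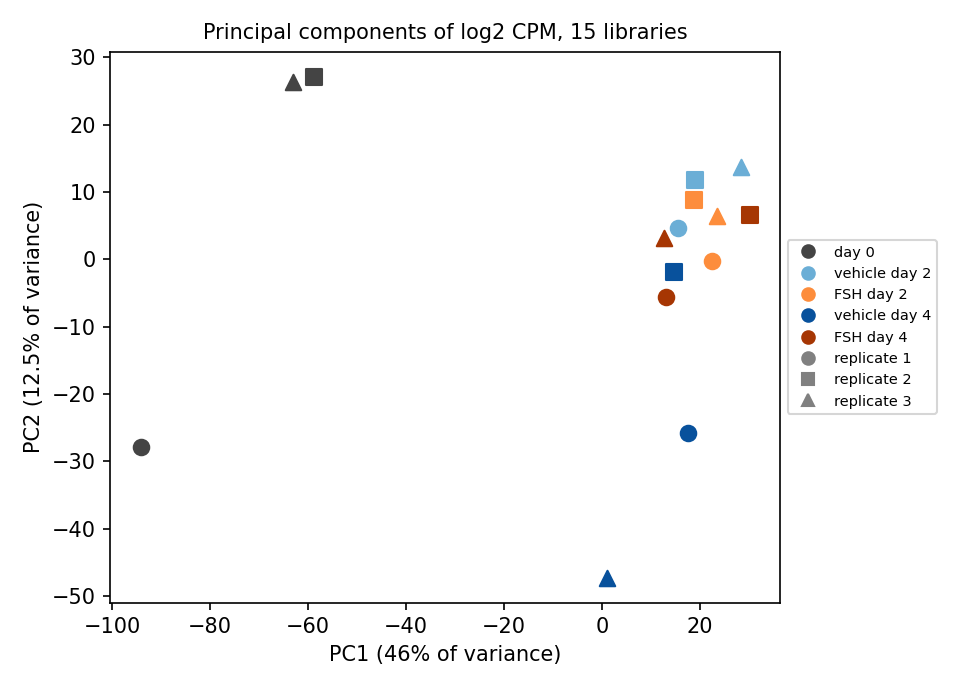
Principal components of log2 CPM over 8207 genes; the axes are the component scores, with 46% and 12.5% of the variance, and each point is 1 of 15 libraries, with colour for the group and shape for the replicate number. The 3 day 0 libraries lie at the low end of the horizontal axis, away from the 12 cultured ones.

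To see what culture alone changed, vehicle day 2 was compared with day 0. Genes of hypoxia and glycolysis rose: 23 of 25 tested members rose (24 when adjusted over the list alone), with a median log2 fold change of 2.75. LDHA, which makes lactate from pyruvate, rose by 4.79 ± 0.30 (SE) and VEGFA, an angiogenic growth factor, by 4.25 ± 0.30, from 59.7 ± 24.8 to 1116 ± 13.5 CPM (SD, n = 3). The glycolytic enzymes PGK1 and ENO1 rose by 3.21 ± 0.27 and 2.75 ± 0.21. The list passed camera at an adjusted p of 6.65e-35, and at an adjusted p = 0.00373 with an estimated correlation. Chaperones and other endoplasmic reticulum stress genes rose in 21 of 22 members (21 when adjusted over the list alone), among them HSP90B1 (2.37 ± 0.26), CALR (2.16 ± 0.25), CRELD2 (2.70 ± 0.31) and PDIA4 (2.10 ± 0.25). Their adjusted p was 8.08e-16, and adjusted p = 0.0477 with an estimated correlation.

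Inflammatory mediators and matrix proteases also rose by day 2. Of 25 inflammatory genes 19 rose and 0 fell (20 and 0 when adjusted over the list alone), with a median of 4.68, or 4.55 with the 4 genes at 0 in a group set at their bound; the adjusted p was 7.63e-13, and adjusted p = 0.0491 with an estimated correlation. PTGS2, the inducible prostaglandin synthase, rose by 4.80 ± 0.56, IL1A by 4.68 ± 0.55 and SOD2, the mitochondrial superoxide dismutase, by 4.35 ± 0.61. The colony-stimulating factor CSF3 went from 1 count to 2238, a ratio of 1970 (353 to 77800), and the chemokine CXCL2 was at least 131-fold higher. Of 19 matrix protease genes 15 rose and 2 fell (17 and 2 over the list alone), at an adjusted p of 3.05e-08 and adjusted p = 0.0215 with an estimated correlation. The gelatinase MMP2 rose by 2.83 ± 0.26 and cathepsin K (CTSK) by 3.05 ± 0.41, while the collagenase MMP1 was at least 102-fold higher. Other large rises were those of SERPINA14 (at least 1100-fold), the neuropeptide precursor NTS (at least 200-fold) and the complement gene CFB (at least 77.4-fold). CFB was at 65.3 ± 43.8 CPM (SD, n = 3). IBSP (at least 91.1-fold) passed at an adjusted p of 0.0286, which was 0.0922, 0.0721 and 0.0644 without day 0 replicates 1, 2 and 3 and 0.0663 and 0.0576 without vehicle day 2 replicates 2 and 3. SLPI (at least 59.8-fold) passed at 0.0312, which was 0.0888, 0.0716 and 0.0736 without day 0 replicates 1, 2 and 3 and 0.0618 and 0.0534 without vehicle day 2 replicates 1 and 2.

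Markers of smooth muscle, steroid-producing and immune cells fell over the same 2 days. Of 15 smooth muscle and pericyte genes 9 fell (12 when adjusted over the list alone), with a median of -1.12, at an adjusted p of 2.52e-07 and adjusted p = 0.0365 with an estimated correlation. The contractile genes ACTA2 and MYH11 fell by 2.50 ± 0.29 and 2.37 ± 0.29, SYNPO2 by 2.66 ± 0.26 and the pericyte marker RGS5 by 2.57 ± 0.26. Of 11 theca and steroidogenesis genes 9 fell (9 over the list alone, adjusted p 4.47e-05), including the luteinizing hormone receptor LHCGR (-3.52 ± 0.83) and the Hedgehog pathway genes PTCH1 (-2.85 ± 0.32) and GLI1 (-3.16 ± 0.59); this call was lost at adjusted p = 0.162 with an estimated correlation. INSL3, a theca cell hormone, fell from 339.5 ± 383.2 to 7.24 ± 10.4 CPM (adjusted p 0.00774, which was 0.0715 without replicate 1 in every group). In the macrophage list 6 of 9 fell (6 over the list alone, adjusted p 0.00311, adjusted p = 0.264 with an estimated correlation), among them CD74 (-4.76 ± 0.65). In the lymphocyte list 4 of 6 fell (4 over the list alone, adjusted p 0.011, adjusted p = 0.098 with an estimated correlation), among them PTPRC (-3.02 ± 0.61) and JCHAIN (-4.56 ± 0.54), the joining chain of secreted antibodies. The lymphatic chemokine CCL21 was 61-fold lower (20.5 to 299), APOA1 45.1-fold (15.1 to 222) and MAL 38.3-fold (12.7 to 189). KCNIP1 (-5.32 ± 0.64) and BRB (-5.22 ± 0.67) fell.

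FSHR, the receptor for FSH, fell by 3.26 ± 0.54 at day 2 (adjusted p 0.000313, edgeR quasi-likelihood test), from 29.6 ± 10.4 to 2.88 ± 2.29 CPM (n = 3). It was also lower at vehicle day 4, by -3.11 ± 0.56 (adjusted p 0.000697) at 3.35 ± 0.89 CPM. INHBA, a subunit of activin and inhibin, rose by 2.15 ± 0.59 at day 2 with an adjusted p of 0.0142, which was 0.0667 without day 0 replicate 1 and 0.0574 without vehicle day 2 replicate 1. At day 4 it was at 1.60 ± 0.59 (adjusted p 0.0608), which passed with the replicate block at 0.0121, without vehicle day 4 replicate 2 at 0.0386 and without vehicle day 4 replicate 3 at 0.027. STAR did not pass at either day (-1.42 ± 0.68 and -0.80 ± 0.67, adjusted p 0.119 and 0.408). The aromatase gene CYP19A1, the oocyte genes GDF9, BMP15 and DDX4 and the listed-at-0 AMH did not pass the filter on low counts. No change in oocyte transcripts was detectable at this depth: only NPM2 and OOEP of the oocyte list could be tested.

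Further lists passed camera at day 2 and lost the call with an estimated correlation, except WNT. In the WNT pathway 9 of 19 fell and 0 rose (9 and 0 when adjusted over the list alone, adjusted p 0.00298, adjusted p = 0.039 with an estimated correlation), among them RSPO3 (-1.93 ± 0.26) and SFRP2 (-3.69 ± 0.62). This list mixes ligands and receptors with inhibitors such as the SFRP genes, so counts of its members give no direction of pathway activity. Of 22 cell proliferation genes 14 fell (14 over the list alone, adjusted p 0.000409, adjusted p = 0.386 with an estimated correlation), with CENPF, a kinetochore protein, at -2.81 ± 0.37. Cholesterol genes rose in 13 of 21 (14 over the list alone, adjusted p 3.66e-06, adjusted p = 0.264 with an estimated correlation), with SQLE at 2.34 ± 0.31. Oxidative stress genes rose in 11 of 22 (12 over the list alone, adjusted p 5.76e-06, adjusted p = 0.0521 with an estimated correlation). Oxidative phosphorylation genes rose in 8 of 23 (8 over the list alone, adjusted p 0.0159, adjusted p = 0.374 with an estimated correlation, 0.0627 without replicate 1, 0.0044 to 0.374 over the alternatives). In the p53 and apoptosis list 5 of 15 rose and 1 fell (5 and 1 over the list alone, adjusted p 0.0479, adjusted p = 0.114 with an estimated correlation); the call was lost with the replicate block at 0.0733, without replicate 2 at 0.0777 and without replicate 3 at 0.0728, with 1.63e-05 to 0.114 over the alternatives. CDKN1A, a cell cycle inhibitor of that list, rose by 2.66 ± 0.27. Ribosomal protein genes rose in 1 of 26 (0 over the list alone, adjusted p 0.0455, adjusted p = 0.69 with an estimated correlation, 0.00444 to 0.69 over the alternatives, 0.326 without replicate 1, the number of the day 0 library with 9.18% of its counts in such genes).

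Members that passed in the remaining lists went both ways or were few. The adjusted p of camera was 0.243 for the granulosa cell, PI3K-AKT-FOXO and interferon lists, 0.306 for cortical stroma, 0.343 for Hippo-YAP targets, 0.373 for FSH and cAMP responsive genes. It was 0.471 for TGF-beta and BMP, 0.752 for heat shock, 0.755 for endothelial genes, 0.968 for immediate early genes and 0.864 for the oocyte, collagen and ovarian surface epithelium lists. For the Hippo-YAP, FSH and cAMP, and collagen lists the median was negative while the test pointed up, and for heat shock the mean was negative while the median and the test were positive. At day 4 the Hippo-YAP and FSH and cAMP medians were again negative with the test up, and the cortical stroma, endothelial and immediate early medians were positive with the test down, and none of these lists passed. In the collagen list 7 rose and 8 fell of 22 (7 and 8 when adjusted over the list alone), the collagen-modifying enzymes LOXL2 (3.06 ± 0.29), P4HA1 (2.11 ± 0.25) and PLOD2 (1.68 ± 0.27) upwards and fibrillin FBN1 (-1.69 ± 0.27) downwards. In the granulosa cell list 4 rose and 7 fell of 15 (5 and 7 over the list alone), the keratin KRT18 by 3.86 ± 0.51 and FSHR as given above. In total 1311 genes rose and 1307 fell, 873 and 930 of them at least 2-fold; the groups did not overlap for 47.1% of genes, where chance gives 10%. The total of 2618 was 1030 without replicate 3 in every group. Beside these changes RN45S went from a mean of 2500 ± 1425 TMM-scaled CPM at day 0 to 1004 ± 149 at vehicle day 2, and GPC5 from 3768 ± 3024 to 424 ± 90.1 (SD, n = 3).

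**Figure D2:**
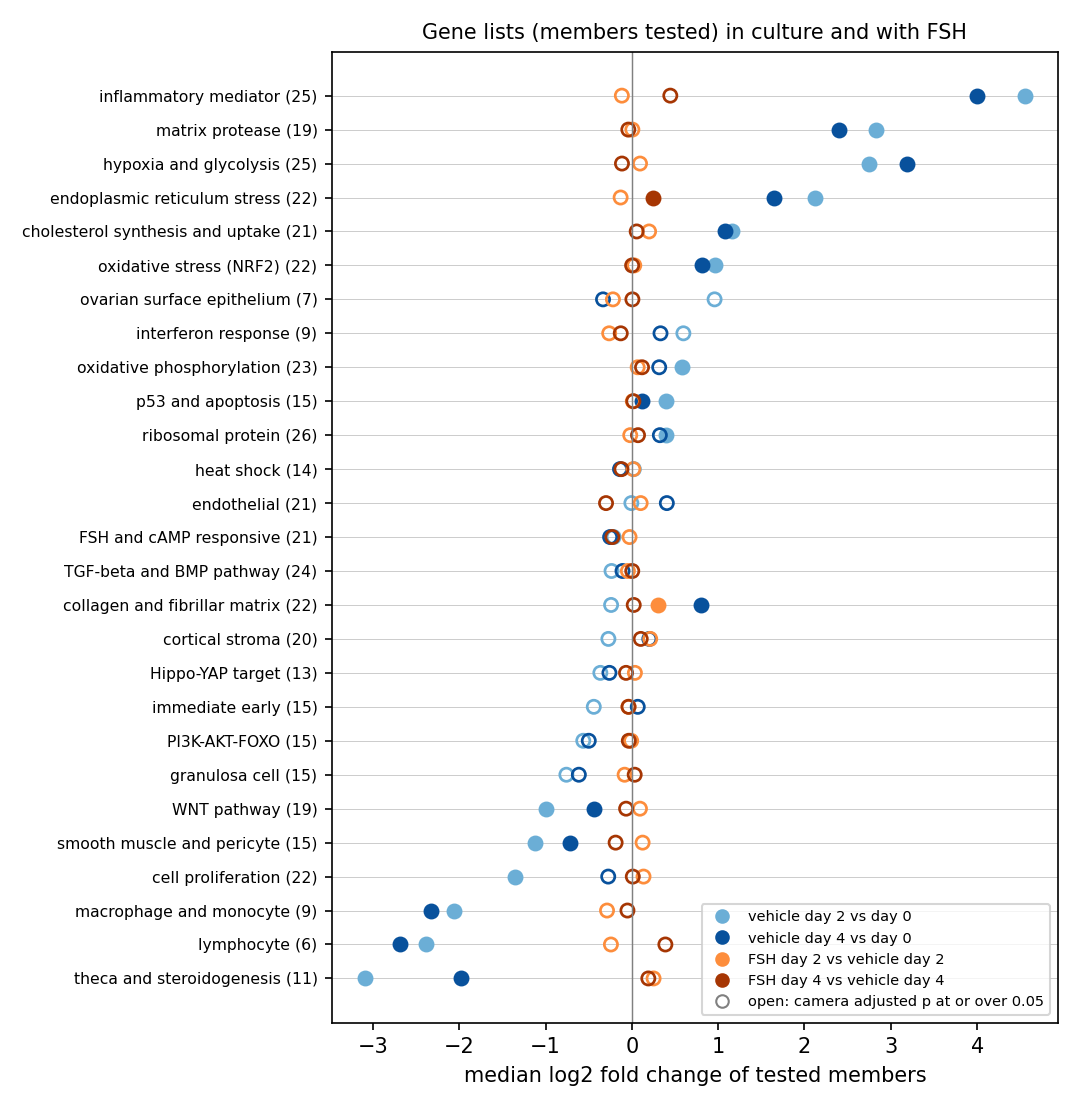
Median log2 fold change (horizontal axis) of the tested members of each gene list with at least 3 tested members (vertical axis, number tested in brackets), with genes at 0 in a group set at their bound; filled circles passed camera at 0.05 with the preset correlation. Hypoxia and glycolysis lies at 2.75 and 3.18 in culture, while the FSH points stay near 0.

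After 4 days in vehicle, 1117 genes were higher and 956 lower than at day 0. All 25 tested hypoxia and glycolysis genes rose (25 when adjusted over the list alone, median 3.18), VEGFA by 5.25 ± 0.31, LDHA by 5.00 ± 0.30 and EGLN3, an oxygen-sensing prolyl hydroxylase, by 5.59 ± 0.36. The adjusted p was 1.06e-53, and adjusted p = 0.000338 with an estimated correlation. Matrix proteases rose in 13 of 19 and fell in 1 (16 and 1 over the list alone, adjusted p 5.64e-09, adjusted p = 0.0197 with an estimated correlation), with MMP1 at least 260-fold and MMP13 at least 62.8-fold higher. SERPINA14 was at least 231-fold and IBSP at least 350-fold higher; without replicate 1 in every group IBSP was at an adjusted p of 0.138. GDF15, a stress-induced cytokine, was at least 70.5-fold and CFB at least 80.2-fold higher. These bounds take the 3 libraries of a group together, and CFB varied widely between them, at 60 ± 64.8 CPM (SD, n = 3). Inflammatory genes rose in 18 of 25 (21 over the list alone, median 4.01, or 3.99 with bounds, adjusted p 2.33e-10, adjusted p = 0.0768 with an estimated correlation). Endoplasmic reticulum stress genes rose in 20 of 22 (20 up and 1 down over the list alone, adjusted p 5.41e-12, adjusted p = 0.0768 with an estimated correlation). Oxidative stress genes rose in 11 of 22 (12 over the list alone, adjusted p 5.43e-05, adjusted p = 0.0768 with an estimated correlation), and cholesterol genes rose in 9 of 21 (12 over the list alone, adjusted p 3e-04, adjusted p = 0.345 with an estimated correlation). CXCL2 was at least 55.1-fold higher at an adjusted p of 0.0193, which was 0.0694 without day 0 replicate 1, 0.0513 without day 0 replicate 2 and 0.0654 without vehicle day 4 replicate 1.

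Collagen and fibrillar matrix genes, which had gone both ways at day 2, rose in 10 of 22 and fell in 2 at day 4 (10 and 2 over the list alone, adjusted p 7.07e-05, adjusted p = 0.173 with an estimated correlation), LOXL2 by 3.99 ± 0.29 and P4HA2 by 1.71 ± 0.19. Both are collagen-modifying enzymes, and mean levels of matrix proteins went both ways. BGN was at 122.1 ± 41.94 CPM against 41.02 ± 14.44 at day 0, and COL1A1 at 1373 ± 370.9 against 1701 ± 907.1 (SD, n = 3). Of 22 cell proliferation genes 0 rose and 0 fell in edgeR (0 and 0 over the list alone, adjusted p 0.416, from 0.0143 without replicate 1 to 0.8 over the alternatives). Genes of the smooth muscle list were also lower than at day 0 (6 of 15 fell, 8 fell and 1 rose over the list alone, adjusted p 0.000458, adjusted p = 0.0812 with an estimated correlation), with MYH11 at -2.65 ± 0.29. Falls were also seen in the theca list (5 of 11, 5 over the list alone, adjusted p 0.000926, adjusted p = 0.239 with an estimated correlation), with PTCH1 at -3.57 ± 0.35, and in the lymphocyte list (3 of 6, 3 over the list alone, adjusted p 0.00222, adjusted p = 0.0701 with an estimated correlation), with JCHAIN at -5.86 ± 0.64. Macrophage genes fell in 5 of 9 (5 over the list alone, adjusted p 0.00889, adjusted p = 0.309 with an estimated correlation, 0.07 without replicate 3, 0.000501 to 0.309 over the alternatives), with CD74 at -2.86 ± 0.57. WNT genes fell in 4 of 19 (4 over the list alone, adjusted p 0.00904, adjusted p = 0.0701 with an estimated correlation, 0.0581 without replicate 3, 9.42e-05 to 0.0701 over the alternatives), with RSPO3 at -2.43 ± 0.27. The p53 list had 4 up and 2 down of 15 (6 and 2 over the list alone, adjusted p 0.0227, adjusted p = 0.0768 with an estimated correlation, 0.0529 without replicate 2, 1.48e-05 to 0.0768 over the alternatives). CCL21 was 139-fold lower (24.6 to 5530), VNN1 62.3-fold (10.8 to 2490), LMO3 48.4-fold (13.1 to 405), WDFY4 43.2-fold (7.41 to 1740) and HHIP 38.9-fold (13 to 191), and QRFPR (-5.22 ± 0.62) and BRB (-5.08 ± 0.70) fell. Beside these changes RN45S was at 1158 ± 531 TMM-scaled CPM and GPC5 at 519.9 ± 242 at vehicle day 4 (SD, n = 3). The 2073 calls became 1119 in a model of both groups alone, 1360 without replicate 1 and 917 without replicate 3.

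The changes at both times ran closely together across genes (Pearson r 0.884, Spearman rho 0.815, genes are not independent replicates). Both comparisons share the day 0 libraries. In 20 simulations day 0 and both vehicle groups were all redrawn from the fitted day 0 means, with the spread shared by all groups. These gave a mean r of 0.495 and rho of 0.469. If the day 0 libraries vary more than that shared spread, the simulated values are too low. The covariance was 1.25 against a simulated 0.096, a difference of 1.15. Of the called genes 807 rose and 756 fell at both times, where independent lists would share 178 and 152, and 3 went in opposite directions. The 3 day 0 libraries were not split between both comparisons, and part of the excess may come from the shared controls.

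Globin genes were the only tested members of the red blood cell list. HBA, the alpha chain of haemoglobin, rose from 1.77 ± 3.07 CPM at day 0 to 507 ± 251 at vehicle day 2 and 2815 ± 1554 at vehicle day 4 (n = 3 each, adjusted p 3.29e-06 and 2.62e-07, edgeR quasi-likelihood test). HBM was 43.1-fold higher at day 2 (7.38 to 1740) and 161-fold at day 4 (28.4 to 6390), against 1 count at day 0. Both members rose at both times (2 when adjusted over the list alone); the list's adjusted p was 0.000302 at day 2, with adjusted p = 0.0521 with an estimated correlation, and 4.7e-07 at day 4, with adjusted p = 0.0247 with an estimated correlation. HBB, the beta chain, had 1 count in the 12 cultured libraries together and 6 at day 0. Reads from near-identical globin copies cannot be separated in these counts.

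**Figure D3:**
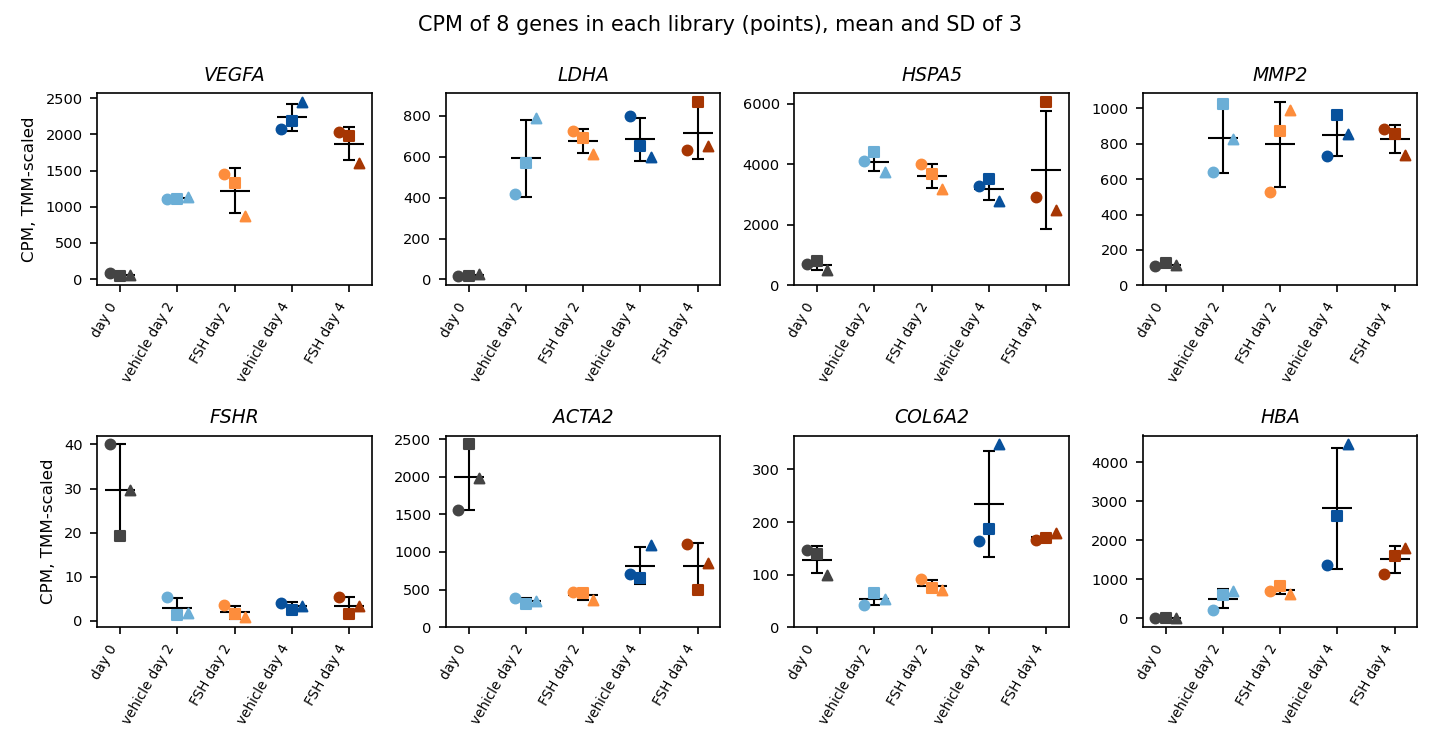
Level in CPM (vertical axes, TMM-scaled) of 8 genes in each of the 15 libraries (points, shape for the replicate number), with the mean and SD of the 3 libraries of each group (horizontal axis). FSHR falls from a mean of 29.6 CPM at day 0 to 2.88 at vehicle day 2, and HBA reaches 2815 at vehicle day 4.

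Between day 2 and day 4 in vehicle, 24 genes rose and 3 fell. The matrix genes COL6A2 (2.12 ± 0.27), COL6A1 (1.61 ± 0.25), COL5A3 (2.32 ± 0.47) and biglycan BGN (2.30 ± 0.43) rose, as did the mitotic genes ASPM (2.71 ± 0.52) and CENPF (2.07 ± 0.37), the myosin light chain MYL9 (1.98 ± 0.35), EGLN3 (1.39 ± 0.27) and HBA (2.47 ± 0.49). The pentraxin PTX3 (-3.32 ± 0.67), LAPTM4B (-1.78 ± 0.37) and the phosphatase PPM1D (-1.12 ± 0.22) fell. Collagen genes as a list moved up with 3 of 22 rising (10 when adjusted over the list alone, adjusted p 9.61e-14, adjusted p = 0.0752 with an estimated correlation). Cell proliferation also moved up (1 of 22, 9 up and 1 down over the list alone, adjusted p 2.99e-07, adjusted p = 0.423 with an estimated correlation). So did hypoxia (1 of 25, 8 over the list alone, adjusted p 2.99e-07, adjusted p = 0.108 with an estimated correlation). Smooth muscle genes moved up (1 of 15, 5 over the list alone, adjusted p 0.00109, adjusted p = 0.225 with an estimated correlation), as did red blood cell genes (1 of 2, 2 over the list alone, adjusted p 0.000109, adjusted p = 0.0752 with an estimated correlation). Endoplasmic reticulum stress (adjusted p 0.0047), inflammatory (0.00557), oxidative phosphorylation (0.0112), heat shock and cholesterol genes (0.0425 each) moved down. These had adjusted p = 0.634 with an estimated correlation, and 0.65 for cholesterol. Over 19 alternatives the genes that fell lost the call often, PTX3 in 13 (adjusted p 0.000128 to 0.662), LAPTM4B in 12 (5e-04 to 1) and PPM1D in 11 (0.000982 to 0.969). Of the genes named as rising, COL5A3 lost it in 12 (0.000683 to 0.741), COL6A2 in 4 (6.18e-09 to 0.464) and the others in 7 to 10. Over the list alone 2 genes fell in each of the stress, inflammatory and oxidative phosphorylation lists and 0 in the heat shock and cholesterol lists. Inflammatory genes did not pass without replicate 3 (0.12), oxidative phosphorylation not without replicate 2 (0.139), heat shock not without replicate 2 (0.24) or 3 (0.0543) and cholesterol not without replicate 1 (0.0799) or 2 (0.139). Over the alternatives these ran from 5.09e-05, 0.00106, 0.00601 and 0.0192 for the inflammatory, oxidative phosphorylation, heat shock and cholesterol lists up to the values with an estimated correlation.

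The 27 genes of this comparison depended on the libraries and the tool. The count was 85 with the replicate block (68 up and 17 down, including all 27), 161 in DESeq2 (107 up and 54 down, including all 27), 11 in limma-voom and 0 in a model of both groups alone. It was 0 without vehicle day 2 replicate 1, 4 without vehicle day 2 replicate 2, 2 without vehicle day 2 replicate 3, 152 without vehicle day 4 replicate 2 and 2 without vehicle day 4 replicate 3, the library with 7212 plain CPM of CLASP1. Leaving out libraries outside the comparison, chosen after the result was seen, gave 146 without day 0 replicate 1, 13 without day 0 replicate 3, 11 and 14 without FSH day 2 replicates 2 and 3, and 3, 3 and 7 without FSH day 4 replicates 1, 2 and 3. At an unadjusted p below 0.05 there were 1183 genes, where 410.4 are given by chance. In simulated 2-fold changes for this comparison 5 of 43 DESeq2 calls were false, against 0 of 29 in edgeR and 0 of 27 in limma-voom.

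FSH was compared with vehicle at day 2 to ask what the hormone added to culture. In edgeR 0 genes passed, and 0 in DESeq2 and limma-voom. At an unadjusted p below 0.05 there were 93, where chance gives 410.4. Vehicle and FSH libraries of the same number correlated at 0.3963, 0.3427 and 0.2734 in their deviations from the group means. The model without the replicate block may thus give p-values that are too large here. The intervals and simulations below, for all FSH effects, also leave out a replicate effect. The groups did not overlap for 6.8% of genes (10% by chance). The smallest p-values belonged to SHISA9 (-2.66 ± 0.73), ENG (0.97 ± 0.27), DTX2 (-1.89 ± 0.53) and PRCP (1.02 ± 0.31), each at an adjusted p of 1; ENG passed when adjusted over the endothelial list alone. FSHR was at -0.59 ± 0.72, INHBA at -0.03 ± 0.56 and STAR at -1.21 ± 0.86. Of the lists, collagen and fibrillar matrix moved up with a median of 0.31 and 0 of 22 members passing in edgeR (0 over the list alone); its adjusted p of 3.18e-06 was lost at adjusted p = 0.652 with an estimated correlation and at 0.29 without replicate 1, and ran from 2.18e-08 to 0.949 over the alternatives. With the replicate block, granulosa cell and endoplasmic reticulum stress genes also moved down and cholesterol genes up, at 0.0477 each. Without the block these lists were at camera adjusted p-values of 0.105, 0.138 and 0.105 with the same preset correlation. With an estimated correlation and no block they were at adjusted p = 0.652, 0.847 and 0.847. FSH and cAMP responsive genes had a median of -0.03 and an adjusted p of 0.573, and granulosa cell genes -0.08 and 0.105. The 95% interval of the fold change lay within 2-fold for 61.8% of genes. In simulated data for this comparison edgeR recovered 0% of genes changed 1.5-fold, 12.5% of those changed 2-fold and 76.5% of those changed 4-fold. DESeq2 recovered 30% of those changed 2-fold, with 9 false calls among 69, and limma-voom 6.5%, with 1 among 14. At 2-fold edgeR made 3 false calls among 28.

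At day 4 the same comparison gave 0 genes in edgeR, DESeq2 and limma-voom, with 528 at an unadjusted p below 0.05, where chance gives 410.4, and a smallest adjusted p of 0.755. The groups did not overlap for 11.6% of genes (10% by chance). The smallest p-values were those of ATG9A (-2.50 ± 0.60), PDE2A (-0.94 ± 0.24), ATP23 (1.16 ± 0.30) and APAF1 (-0.82 ± 0.21). FSHR was at 0.10 ± 0.67, INHBA at -0.35 ± 0.57 and STAR at -0.47 ± 0.73. Endoplasmic reticulum stress genes moved up with a median of 0.24 and 0 of 22 members passing in edgeR (0 over the list alone, adjusted p 0.0117, adjusted p = 0.973 with an estimated correlation, 0.391 without replicate 2, 0.000586 to 0.994 over the alternatives). MANF, a secreted stress-response protein, was at 1.07 ± 0.39, with 258.6 ± 166.2 CPM under FSH and 122.7 ± 43.97 under vehicle (SD, n = 3). HSPA5 of the same list was at 6066 CPM in FSH day 4 replicate 2 and at 2916 and 2479 in replicates 1 and 3. In the vehicle day 4 libraries it was at 2780 to 3522. Ribosomal protein genes did not pass (median 0.07, adjusted p 0.306, adjusted p = 0.973 with an estimated correlation, 8.66e-11 to 0.994 over the alternatives). The list passed upwards without replicate 1 (0.000543), without replicate 3 (3.33e-05) and without day 0 replicate 1 and vehicle day 4 replicate 3 (8.66e-11), the latter with 19.12% of its counts in such genes. FSH and cAMP responsive genes had a median of -0.23 and an adjusted p of 0.973; for granulosa cell genes the median was 0.03 although the test pointed down (adjusted p 0.992). The 95% interval lay within 2-fold for 51% of genes, and simulations recovered 13.5% of genes changed 2-fold and 83.5% of those changed 4-fold.

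Averaged over both days, FSH again gave 0 genes in edgeR, DESeq2 and limma-voom (172 at an unadjusted p below 0.05, where chance gives 410.4), with PSTPIP2 (-2.87 ± 0.74), TPRN (-1.33 ± 0.37), NDUFB7 (0.73 ± 0.21) and ENG (0.63 ± 0.19) at the smallest p-values. The smallest adjusted p of a list was 0.0903 (collagen, upwards, adjusted p = 0.944 with an estimated correlation). It passed with the replicate block at 0.0263, without replicates 2 and 3 at 0.00818 and 0.00128 and without day 0 replicate 1 and vehicle day 4 replicate 3 at 0.0316, with 0.00128 to 0.954 over the alternatives. Cortical stroma (0.158, upwards, adjusted p = 0.944 with an estimated correlation) passed with the block at 0.0325, without replicate 2 at 0.00549 and without that pair of libraries at 0.0181, with 0.00549 to 0.954 over the alternatives. Ribosomal protein genes (0.368, upwards, adjusted p = 0.944 with an estimated correlation) passed without replicate 1 at 0.000914, without replicate 3 at 0.0119 and without the pair at 2.62e-07, with up to 0.953 over the alternatives. The 95% interval lay within 2-fold for 81% of genes, and simulations recovered 55% of genes changed 2-fold. The FSH effects of the 2 days correlated at r -0.141 and rho -0.163 across genes, with the same sign for 43.8%. Their difference was past the threshold for 0 genes in edgeR, DESeq2 and limma-voom (364 at an unadjusted p below 0.05, where chance gives 410.4, smallest adjusted p 0.96). Ribosomal protein genes in the difference (0.323, upwards, adjusted p = 0.986 with an estimated correlation) passed without replicate 1 at 0.0127, without replicate 3 at 0.00105 and without the pair at 6.9e-07, with up to 0.988 over the alternatives. The smallest p-values of the difference were those of ARMCX2 (-1.80 ± 0.46), RBM47 (3.60 ± 0.95), XXYLT1 (1.62 ± 0.44) and PTPN18 (-1.80 ± 0.49).

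Tissue cultured with FSH differed from day 0 in 2610 genes at day 2 (1297 up and 1313 down) and in 2240 at day 4 (1130 up and 1110 down). The former count was 1123 without replicate 3. The latter was 1398 without FSH day 4 replicate 2, 1123 without replicate 2 and 1122 without replicate 3. FSH day 4 against FSH day 2 gave 0 genes in edgeR and limma-voom and 9 in DESeq2, with 424 at an unadjusted p below 0.05, where chance gives 410.4. It gave 3 without FSH day 2 replicate 1 and 7 without replicate 1.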

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

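The test of fewer libraries, the splits of the libraries and, among the alternatives, leaving out day 0 replicate 1 and vehicle day 4 replicate 3 together were chosen after the results were seen. For 3 lists a result was singled out because the effect of FSH differed between days by a test of the difference itself. Endoplasmic reticulum stress genes had a median FSH effect of -0.13 at day 2 and 0.24 at day 4 (median difference 0.42, adjusted p 0.00224; adjusted p = 0.83 with an estimated correlation; 0.261 without replicate 2), with 0 of 22 members passing. For collagen genes the medians were 0.31 and 0.02 (median difference -0.31, adjusted p 0.0257; adjusted p = 0.83 with an estimated correlation; 0.352 without replicate 1 and 0.0956 without replicate 2). For hypoxia genes they were 0.09 and -0.11 (median difference -0.13, adjusted p 0.0257; adjusted p = 0.83 with an estimated correlation; 0.494 without replicate 1 and 0.1 without replicate 2). Over the alternatives the adjusted p ran from 0.000164 to 0.881 for stress, from 0.000326 to 0.881 for collagen and from 4.61e-05 to 0.881 for hypoxia.

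A further result was singled out because the change from day 0 in vehicle differed between days for 27 genes, with collagen VI, biglycan and mitotic genes up at day 4. Vehicle day 4 replicate 3 is a candidate source, since the count is 2 without it and the median change of these genes, in the direction called, was 1.43 without it, 1.8 with all libraries and 1.75 to 1.98 without each other vehicle library. That library lowered the median most when left out. The genes kept a median of 1.43 in the direction called without it. They were picked from these same libraries, so this median cannot decide whether that library alone sets the difference. The loss of calls may come from fewer libraries, since 3 of the 5 other vehicle libraries also took the count to 0, 4 or 2 when left out (vehicle day 2 replicates 1, 2 and 3), and this stays open because the count was 25 without vehicle day 4 replicate 1 and 152 without replicate 2. The real split of the 6 vehicle libraries was 1 of 10 that gave as many genes, with at most 0 in the others, and 10 splits are too few for a share under 0.05; a difference between days of culture, which the design names, stays open.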

How the results depend on the processing

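Leaving out libraries outside a comparison, and leaving out day 0 replicate 1 and vehicle day 4 replicate 3 together, were chosen after seeing the data; other alternatives were planned. Counts for both vehicle comparisons and both FSH comparisons with day 0 stayed within 1.5 times under DESeq2, limma-voom, other scalings, filters, non-robust dispersion, the replicate block and without day 0 replicate 1 (2015, 1780, 2049 and 1702 genes for vehicle day 2, vehicle day 4, FSH day 2 and FSH day 4). Exceptions were vehicle day 4 in a model of the compared groups (1119) and some leave-outs. With these, vehicle day 2 ranged from 1030 (replicate 3) to 2775, vehicle day 4 from 917 (replicate 3, with 1360 without replicate 1) to 2075, FSH day 2 from 1123 (replicate 3) to 2808 and FSH day 4 from 1122 (replicate 3, with 1123 without replicate 2 and 1398 without FSH day 4 replicate 2) to 2365. Fewer libraries leave fewer residual degrees of freedom. The counts of 0 for FSH against vehicle at each day, averaged and for the difference stayed 0 in every alternative run.

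For vehicle day 4 against day 2 (27 genes) DESeq2 gave 161, limma-voom 11, a model of the compared groups 0, the replicate block 85 and day 0 replicate 1 and vehicle day 4 replicate 3 left out together 3. Leave-outs ranged from 0 (vehicle day 2 replicate 1; replicate 2; replicate 3) to 152 (vehicle day 4 replicate 2); outside libraries gave 3 to 146. FSH day 4 against day 2 (0 genes) gave 9 in DESeq2 and 3 to 7 without FSH day 2 replicate 1 or replicate 1. The cause was not tested.

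Lists called fell from 16, 14, 10, 1, 1 and 3 (vehicle day 2 and day 4 against day 0, vehicle day 4 against day 2, FSH day 2, FSH day 4, interaction) to 6, 3, 0, 0, 0 and 0 with an estimated correlation. With fry, which does not compare a list with other genes, they were 18 and 17 for vehicle day 2 and day 4 against day 0, 3 for vehicle day 4 against day 2 and 0 for FSH day 2, FSH day 4 and the interaction. Granulosa cell (down), PI3K-AKT-FOXO (down) and Hippo-YAP (up, with negative medians) lists gained the call with it at day 2 (0.0341, 0.00358 and 0.0488) and at day 4 (0.00993, 0.00223 and 0.00892), and ribosomal protein genes lost it at day 2 (0.115). The replicate block gave 4 for FSH day 2 and 2 for the FSH mean (0 without the block), and 0.033 for red blood cell genes, downwards, in the interaction. That list was at 0.129 without the block, adjusted p = 0.83 with an estimated correlation, and 0.0152 without replicate 3. Among lists it changed no other call than these and those given beside the results, and among named genes it brought 12 past the threshold and ended 0 calls. Without replicate 1, 2 or 3 lists ranged from 2 to 7 for FSH day 2, 2 to 3 for FSH day 4, 2 to 5 for the FSH mean and up to 7 (replicate 1) and 6 (replicate 3) for the interaction. Without that pair of libraries they were 2 for FSH day 4 and 4 for the FSH mean. At FSH day 2 hypoxia passed without replicate 3 (from 0.14 to 4.78e-06) and theca without replicate 2 (from 0.319 to 4.4e-05). At FSH day 4 endothelial genes passed without replicate 2 (from 0.734 to 0.00154). Vehicle day 4 against day 2 gained ribosomal protein (0.00151) and theca genes (0.0168) without the pair. It gained cortical stroma (0.0193) without replicate 3. In the interaction with all libraries, cell proliferation (0.98) and endothelial genes (0.468) did not pass. Without replicate 1 they passed at 0.0337 and 0.0127, each in the direction opposite to that with all libraries. Endothelial genes passed at 0.000236 without replicate 2, in the direction they had with all libraries, so these leave-outs gave calls in opposite directions. The highest values over the leave-outs were 0.418 and 0.0722. The cause was not tested.

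Depth limits the lowest genes: 3 counts are 2.11 to 4.22 plain CPM in 1 library.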

Other observations

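GLI2, SMO, SUFU and PDPN, the grouping of genes by Hedgehog pathway and lymphatic vessel, the globin tests, the splits and the test on day 0 replicate 1 were chosen after the values were seen. No list of Hedgehog genes was fixed or tested. In culture PTCH1 fell by 2.85 ± 0.32 at day 2 and 3.57 ± 0.35 at day 4, GLI1 by 3.16 ± 0.59 and 3.38 ± 0.64 and GLI2 by 1.48 and 1.18 (adjusted p 0.0134 and 0.0474, edgeR quasi-likelihood test). HHIP was 38.9-fold lower at day 4 (13 to 191), while the signal transducer SMO, at -0.01 and -0.05, and the pathway inhibitor SUFU, at -1.34 and -1.35 (adjusted p 0.0851 and 0.11), did not pass. PTCH1 and GLI1 also belong to the theca list. Lymphatic vessel genes did not move together: CCL21, PROX1 and MMRN1 fell at both days (PROX1 at day 2 not without replicate 2, adjusted p 0.0552). LYVE1 rose by 3.39 ± 0.57 at day 2 and was at 1.66 ± 0.58 at day 4 (adjusted p 0.0486), and PDPN rose by 2.32 ± 0.27 and 2.69 ± 0.27.

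HBA and HBM counts were far higher in cultured than in uncultured tissue. Red blood cells in the tissue would bring their other transcripts. The 7 other red cell genes together reached at most 2.11% of HBA plus HBM in any cultured library, and HBB had 6 counts beside 7 of HBA at day 0 but 1 beside 18541 in culture, which argues against red blood cells. Depth does not account for it, since the lowest cultured HBA level was 41.8 times the highest at day 0 (222 against 5.31 CPM). Reads shared with a near-identical alpha-like globin stay open, as only 1 other alpha-like gene, HBQ1, had counts, so that a copy read as HBA cannot be told apart; induction of HBA in cultured cells may be a further explanation, untested here.

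For the 2618 genes of vehicle day 2 against day 0, 71.2% kept call and direction without day 0 replicate 1 (1865 genes), and 2026 genes were called after thinning every library to 711446 counts, so neither that library nor depth alone accounts for them. For single comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. The real split was 1 of 10 with as many genes for vehicle day 2 (2618, highest other 0), vehicle day 4 (2073, highest other 66), FSH day 2 (2610, highest other 0) and FSH day 4 (2240, highest other 0) against day 0. The 66 came from the split that put day 0 replicate 1 with vehicle day 4 replicates 1 and 3. The 3 other splits of vehicle day 2 and day 0 libraries that part all 3 replicate pairs gave at most 0. For FSH against vehicle at each day and FSH day 4 against day 2 the real count and the highest other were 0. For the FSH mean and the interaction the real count was 0 and the others reached 11 and 8 genes. Every split reaches a count of 0, all 100 drawn ones included, so these splits test nothing.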
